A study of Oryza sativa Japonica Group with 6 samples.

How the data were processed

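Coleoptiles of wild-type and *rad* mutant rice (both cultivar Kinmaze) were compared on 6 arrays. Per the labels' protocols, 15 seeds were sown in a bottle with 1 L of deionized water and germinated under submergence; seedlings were fixed and frozen, sections of 8 µm were made, coleoptiles were collected by laser microdissection, and RNA was amplified linearly into Cy3- and Cy5-labelled cRNA. Each array carried mutant RNA in one dye and wild-type RNA in the other. Titles number 3 replicates, each with a colour swap, and the labels give the dye of each genotype, which set the direction of every ratio.

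Per the file headers, the arrays were of Agilent design 012106 with 22575 spots and were read with Feature Extraction 8.5.1.1. The deposited scanner files give the mean intensity of each spot and the median intensity of its local background in each channel, with no normalization. Per the file headers they also hold processed intensity values, from which a fitted background surface was subtracted and which were dye-normalized within the array (linear and LOWESS), and a log10 ratio of Cy5 over Cy3. The deposited value table of the series holds log10 ratios: set against the scanner's log10 ratio spot by spot, each column matched it to within 5e-06, with the sign turned on the colour-swapped arrays, so that all columns run as mutant over wild type. No further scale or centring was applied there; column medians lay between -0.000509 and 0. Other deposited columns used were flags of 0 or 1 per spot, per the file headers. How RNA was pooled before labelling is not given in the sources used here.

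Ratios were computed from the mean and background intensities with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50, and each array was normalized by loess with control spots at weight 0. Control spots were left out, as were spots that the scanner software marked as non-uniform or population outliers, between 28 and 82 per array. A probe was kept when it was well above background in either genotype on at least 4 of the 6 arrays: 20213 of 21495 probes passed, and 266 of these were left out for an outlier spot on any array, which left 19947. Ratios were turned to mutant over wild type and the arrays of each dye-swap pair were averaged, because a colour swap of the same replicate is a technical repeat, which gave 3 replicates. A dye effect cancels in these means. An intercept was fitted with lmFit and eBayes (two-sided, total degrees of freedom 4.26), and a probe was called at a Benjamini-Hochberg adjusted p under 0.05. Saturated spots were kept, between 32 and 53 per array in Cy5 and 4 to 6 in Cy3. Of the probes named none was below background in a genotype on every array. The *PDC1* probe (AK100678) was saturated in Cy5 on all 6 arrays and an HSP70 probe (AK109474) in the mutant on 3, so their mean ratios are not given as sizes.

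That same-numbered arrays belong together comes from the titles. Deviations from the mean of their dye orientation correlated between the arrays of a pair (r = 0.805, 0.663 and 0.840 across genes for replicates 1, 2 and 3), against -0.662 to -0.115 between arrays of different numbers. Ratios within dye-swap pairs correlated at 0.882 to 0.896. The smallest share of probes well above background in a channel was 90.4%. Each slide held a single array.

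Every probe on the array stands for its own cDNA, so probes are named by the cDNA accession of the file and by its description, which is a best match and often from another species; cDNAs with the same description may come from 1 gene. The gene table for the reference assembly GCF_034140825.1 matched 0 of the accessions, so loci, chromosomes and positions are not given. Of the probes tested 8118 had a description with a named product.

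Before the data were examined, 34 gene lists were fixed as text patterns on the descriptions; locus numbers in those lists could not be used. The 32 lists with at least 3 measured probes were tested with camera (preset inter-gene correlation 0.01, two-sided, Benjamini-Hochberg over lists), with camera under an estimated correlation, which rests on 2 residual degrees of freedom, and with fry. The genes named were also chosen by a rule fixed then: the 10 largest rises and 10 largest falls among called probes with a named product and the same sign in all 3 replicates and on all 6 arrays; all measured fermentation cDNAs; 4 members with the smallest p from each called list; and up to 2 called members of each other list. Descriptions that give only a clone or locus name, or say unknown or hypothetical, did not count as named products. The text pattern for this was completed after the top of a trial ranking had been seen, so that part of the rule was not fixed beforehand. The haemoglobin cDNAs were named after their values were seen. After the largest changes had been seen, 12 further lists were written as text patterns. The patterns of the mitosis list and of the H2A and H2B list were corrected after a first run, because they had also matched words such as recycling, tetracycline and ALDH2b.

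The procedure was tested on simulated arrays for this comparison, with 20213 probes, a dye effect, spreads drawn from the real arrays and 200 changed probes. It recovered 40.3% of those changed by 0.5 on the log2 scale, 86.6% of those changed by 1 and 98.5% of those changed by 2, in the right direction, and called 4 unchanged probes. Of 200 random lists of 20 probes it called 0 with camera. Simulated probes varied independently of each other and these lists held unchanged probes only. That result therefore says nothing about correlation between the genes of a real list. In the data 24.7% of the tested probes were called, a larger share than was changed in the simulation, so the recovery there may differ. The simulated spread also differed from that of the data. Technical noise was added to the spread of the pair means, which already holds it, and spreads were shuffled over probes.

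Alternatives were the scanner's processed signals with and without loess, no background subtraction, normexp with no offset, median centring, Aquantile scaling, no filter or a strict filter on dim probes, the 6 arrays with and without the replicate block or with a dye term, each dye orientation alone, each replicate left out, the deposited value table, and eBayes with trend and robust. Chosen after seeing the data were 1 probe per description, the ribosomal list without plastid descriptions, the fermentation list without its saturated probe, and list tests on the fits with the replicate block (cameraPR on moderated t-statistics). Of these, 1 probe per description lies nearest to the planned 1 probe per locus.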

Results

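Transcript levels were compared in the coleoptile, the sheath that encloses the first leaf of a grass seedling, between wild-type rice of the cultivar Kinmaze and the *rad* mutant. The series describes the mutant as having reduced alcohol dehydrogenase (ADH) activity. Seeds had germinated under water, where ethanol fermentation by pyruvate decarboxylase (PDC) and ADH regenerates the NAD+ that glycolysis needs without oxygen. The coleoptile was cut out of frozen sections of 8 µm by laser microdissection. Mutant and wild type were hybridised against each other on 6 two-colour arrays, as 3 replicates that were each measured in both dye orientations. Each value below is a mean log2 ratio of mutant over wild type ± SD over 3 replicates (n = 3). Between 90.4% and 95.7% of the probes were well above background per channel, and the median signal was 3.998 to 10.3 times the local background. The number of arrays limits the precision. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The nature of the *rad* lesion is not in the labels, and the level of ADH transcripts therefore checks nothing about the labels.

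The mutant coleoptile differed from the wild type over a wide range of transcripts. Of 19947 probes tested with limma, 2920 were higher and 2009 were lower in the mutant after Benjamini-Hochberg adjustment. Most changes were small, with a median size of 0.39 on the log2 scale, whereas 357 probes rose and 164 probes fell at least 2-fold. All 4929 changed probes had the same sign in all 3 replicates, and 4763 had it on all 6 arrays. A call over 3 replicates largely requires such agreement, so it is no separate support. Without replicate 1 the count of changed probes was 1491 and without replicate 2 it was 1184, whereas it was 4573 without replicate 3, each from a fit with 1 replicate fewer. Replicate 3 correlated less with replicates 1 and 2 across genes (r = 0.755 and 0.840) than these did with each other (r = 0.885); genes are not independent replicates.

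**Figure D1:**
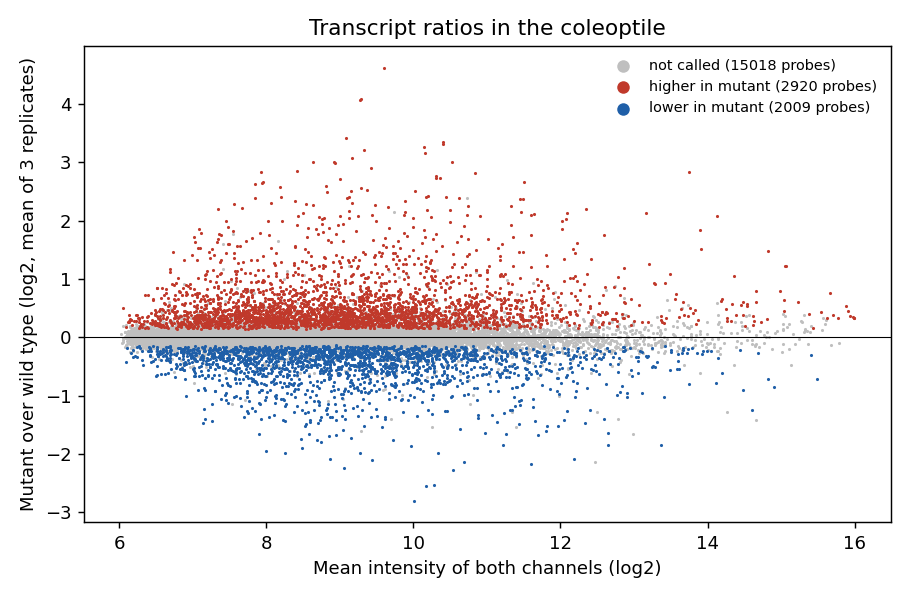
Mean log2 ratio of mutant over wild type over 3 replicates (vertical axis) against mean log2 intensity of both channels (horizontal axis) for 19947 probes. Red points are the 2920 probes higher and blue points the 2009 probes lower in the mutant (limma, adjusted), and grey points were not called.

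The largest rises among probes with a named product included a glutathione S-transferase, a chitinase and a calcium-binding protein. A pair of cDNAs described as OsGSTU6, a tau-class glutathione S-transferase of the type that conjugates toxic compounds, were higher by 3.35 ± 1.22 (AK103699, 10.2-fold, adjusted p = 0.0155) and 3.32 ± 1.26 (AK059760); they share a description and may be 1 gene. A small EF-hand calcium-binding protein like wheat CCD1 (AK109278) rose by 3.26 ± 0.23, or 9.60-fold (adjusted p = 0.00204). A chitinase (AK101155), an enzyme that degrades fungal cell walls, rose by 3.07 ± 0.51, and PBZ1 (AK071613), a probenazole-inducible defence protein, by 3.00 ± 1.82 (adjusted p = 0.0496). A secreted glycoprotein-like cDNA (AK107370) rose by 3.00 ± 0.41, a cytochrome P450 (AK063764) by 2.86 ± 0.25, a putative phospholipase (AK062368) by 2.82 ± 0.60, a cinnamoyl-CoA reductase-like cDNA (AK064401) by 2.77 ± 0.80 and Rtac1 (AK103051) by 2.73 ± 0.33. The size of several rises differed between replicates: AK103699 read 3.89 in replicate 2 but 1.96 in replicate 3, and AK071613 read 1.04, 4.62 and 3.34 in replicates 1, 2 and 3. The call of AK071613 was also lost without background subtraction (adjusted p = 0.0562), without a filter on dim probes (0.0524) and on the arrays with the mutant in Cy3 (0.0506). Leaving out replicate 1 ended the calls of AK103699 and AK059760 (adjusted p = 0.0881 and 0.0995). Leaving out replicate 2 ended those of both and of AK071613 and AK064401 (adjusted p = 0.0825, 0.0842, 0.141 and 0.0593), and leaving out replicate 3 ended that of AK071613 (adjusted p = 0.117).

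The largest falls among named products included glycoside hydrolases and mitotic proteins. A beta-glucosidase isozyme (AK066710) fell by 1.99 on the log2 scale (SD 0.69), to 3.98-fold lower levels (adjusted p = 0.0140), and a banana-like beta-glucosidase (AK067934) by 1.86 (SD 1.07). An O-methyltransferase-like cDNA (AK106179) fell by 1.98 (SD 0.06), an LNP-like nucleotide phosphohydrolase (AK069955) by 1.96 (SD 0.10), a golli-interacting protein-like cDNA (AK111332) by 1.89 (SD 0.46), a transmembrane protein (AK058323) by 1.85 (SD 0.80) and the early nodulin OsENOD93a (AK105832) by 1.84 (SD 1.09, adjusted p = 0.0470). The remaining members were cyclin B2 (cycB2;os;1, AK070211), a regulator of entry into mitosis, at -1.76 ± 0.48, a homologue of p55cdc and fizzy (AK102954), which activate the anaphase-promoting complex, at -1.74 ± 0.16, and a kinesin-like microtubule motor (AK101769) at -1.73 ± 0.42. For AK067934 and AK105832 the change was smaller in replicate 3, at -0.68 and -0.59, than in replicate 1, at -2.77 and -2.50. Without replicate 1 the calls of AK111332, AK067934, AK058323, AK105832, AK070211 and AK101769 were lost, with adjusted p between 0.0544 (AK111332) and 0.207 (AK105832). Without replicate 2 those of AK066710, AK067934, AK058323, AK105832 and AK070211 were lost, with adjusted p between 0.0536 (AK070211) and 0.185 (AK105832), and without replicate 3 none of these 10 was lost. AK105832 was also not called without background subtraction (adjusted p = 0.0513).

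Because the mutant is defined by ADH activity, the cDNAs of ethanol fermentation were examined as a list. Of the 4 PDC probes 2 that were not saturated were called higher in the mutant, and PDC2 was not called. No ADH probe in this list was called lower. Outside it, a glutathione-dependent formaldehyde dehydrogenase (AK099733) was called lower (-0.56, limma adjusted p = 0.00618). It entered the aldehyde dehydrogenase list because its name contains those words. The fermentation list also covered class III alcohol dehydrogenases, but only by that wording. List membership therefore says nothing about the enzyme class of AK099733. The RRJ2 PDC cDNA (AK100501) rose by 1.51 ± 0.67, or 2.84-fold (adjusted p = 0.0239), with 0.87, 1.46 and 2.19 in replicates 1, 2 and 3. A cDNA like maize *pdc2* (AK069905) rose by 0.79 ± 0.34 (adjusted p = 0.0231). Both calls were lost without replicate 1 (adjusted p = 0.0525 and 0.121) and without replicate 2 (0.107 and 0.0561). The *PDC1* probe (AK100678) passed the test (adjusted p = 0.0146) but was saturated in Cy5 on all 6 arrays, in the mutant on 3 and in the wild type on 3. Its ratio was -0.13 with the mutant in Cy5 and 1.66 with the mutant in Cy3, so neither a size nor a direction can be read from it. In a fit of the 6 arrays with the replicate as a random block, *PDC1* was not called (adjusted p = 0.184), whereas *ADH2* (AK102799) and the other *ADH1* probe (AK073964) were called higher (adjusted p = 0.0395 and 0.0210). With a dye term added both ADH probes were called as well (0.0146 and 0.0226), and so was the saturated *PDC1* probe (0.00149). On the arrays with the mutant in Cy5 *ADH2* read 0.50 and was called (adjusted p = 0.0190), and on those with the mutant in Cy3 it read 0.16 and was not (0.308). AK073964 was called with the mutant in Cy3 (0.0391) and not with the mutant in Cy5 (0.202). With eBayes trend and robust *ADH2* was called (0.0472). *ADH1* rose slightly on one probe, by 0.21 ± 0.07 (AK069330, adjusted p = 0.0310), but not on the other (AK073964, 0.24 ± 0.17, adjusted p = 0.0905). The call of AK069330 was lost with the scanner's processed signals (adjusted p = 0.0504) and with normexp with no offset. It was also lost on the arrays with the mutant in Cy5 (0.13, adjusted p = 0.122) and without any 1 of the 3 replicates (adjusted p = 0.0659, 0.182 and 0.0864). *ADH2* read 0.33 ± 0.23 (AK102799, adjusted p = 0.0785), a maize Adh2-N-like cDNA read -0.06 ± 0.09 (AK101288, adjusted p = 0.454) and *PDC2* read 0.26 ± 0.42 (AK101594, adjusted p = 0.328).

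As a list, 4 of the 8 fermentation probes, the saturated *PDC1* probe among them, were called higher and 0 lower over all probes, and 6 were higher adjusted over the list alone. The list was called higher by camera (median 0.30, adjusted p = 0.0297), but not with an estimated correlation (adjusted p = 0.589) and not by fry (adjusted p = 0.0789). The call was lost without the saturated *PDC1* probe, in a test chosen after seeing the data. Then 3 of 7 probes were higher and 5 adjusted over the list alone, and camera did not call the list (median 0.26, adjusted p = 0.0554). No other member was left out in this way, so the loss is not shown to be particular to that probe. With all 8 probes the list was also not called without replicate 3 (adjusted p = 0.0564), on the arrays with the mutant in Cy5 alone (adjusted p = 0.141) or with 1 probe per description (adjusted p = 0.0728). Of the 4 calls among single probes, 0 held without replicate 1, 1 without replicate 2 and 3 without replicate 3. The call that held without replicate 2 was that of the saturated *PDC1* probe, which was also 1 of the 3; limma gave 5 of the 8 probes an unadjusted p under 0.05 without replicate 1.

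**Figure D2:**
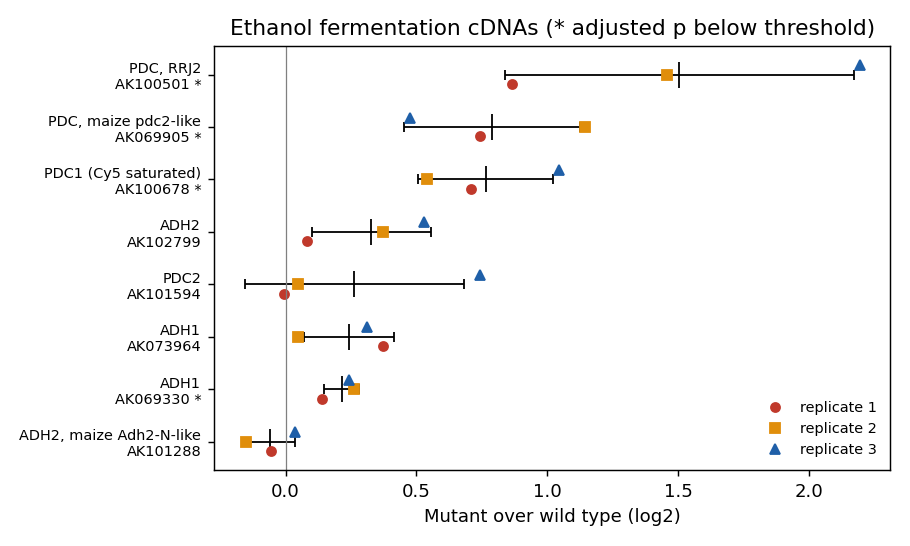
Log2 ratio of mutant over wild type (horizontal axis) for the 8 measured cDNAs of ethanol fermentation, with a symbol per replicate, a vertical tick at the mean and a bar of 1 SD to each side. The RRJ2 PDC cDNA (AK100501) lay at 0.87, 1.46 and 2.19, and asterisks mark the 4 probes called by limma.

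WRKY transcription factors, many of which act in defence and stress responses, were higher in the mutant as a list. Of 23 WRKY probes 11 rose and 0 fell, with 13 higher adjusted over the list alone, and camera called the list (median 0.19, adjusted p = 0.00125; adjusted p = 0.442 with an estimated correlation). Homologues of WRKY57 (AK069091, 1.63 ± 0.19), WRKY3 (AK061266, 1.38 ± 0.08), WRKY50 (AK108522, 1.33 ± 0.25) and WRKY6 (AK105509, 1.26 ± 0.11) rose most firmly.

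Histones, which package newly made DNA, were lower: 8 of 13 probes fell and 0 rose, likewise adjusted over the list alone, with a median of -0.59 (camera adjusted p = 0.000581; adjusted p = 0.442 with an estimated correlation). The histone H4 cDNAs AK058741, AK059019 and AK105816 stood at -1.47 ± 0.29, -1.40 ± 0.18 and -0.79 ± 0.09, and a centromeric histone H3-like cDNA (AK101975) at -0.59 ± 0.06. The call of AK058741 was lost without replicate 1 (adjusted p = 0.0508). Several histone probes share a description, and with 1 probe per description the list was not called (adjusted p = 0.0645). That alternative was chosen after seeing the data, but it lies nearest to the 1 probe per locus planned beforehand.

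Ribosomal proteins, in a list meant for cytosolic ones, were slightly lower, with 48 of 145 probes down and 2 up, and 60 down and 4 up adjusted over the list alone (median -0.13, camera adjusted p = 2.97e-08; adjusted p = 0.442 with an estimated correlation). Part of this list is not cytosolic: the pea-like CL24 (AK060024, -0.60 ± 0.11), among the 4 members with the smallest p, is a plastid protein by its description. The others were an L13 homologue (AK104146, -0.73 ± 0.14) and an S5 protein (AK065820, -0.48 ± 0.02), whose descriptions name no compartment, and a 60S protein (AK063752, -0.41 ± 0.03). Without the 7 probes whose description says plastid, 42 of 138 fell, with a median of -0.11 (adjusted p = 2.61e-07). Plastid members whose description does not name the compartment are not removed by that rule, so the fall is not shown to be one of cytosolic ribosomes alone. Proteasome subunits, which degrade tagged proteins, fell by little: 8 of 56 were lower and 0 higher, but only 3 were lower adjusted over the list alone (median -0.07, camera adjusted p = 0.00945; adjusted p = 0.442 with an estimated correlation). They included OsPBC1 (AK070915, -0.30 ± 0.06), OsPBA1 (AK104152, -0.26 ± 0.05), OsRPN9b (AK068605, -0.24 ± 0.05) and OsRPT5a (AK101474, -0.21 ± 0.05). All 4 of these calls were lost without replicate 1 (adjusted p 0.0587 to 0.0815) and without replicate 2 (0.0871 to 0.166), and those of AK068605 and AK101474 also without replicate 3 (0.0509 and 0.0699). The proteasome call was lost on the arrays with the mutant in Cy3 (adjusted p = 0.643) and with 1 probe per description (adjusted p = 0.0702).

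Expansins, which loosen the cell wall during elongation, were lower as a list: 8 of 31 probes fell and 1 rose, or 9 and 1 adjusted over the list alone (median -0.09, camera adjusted p = 0.0324; adjusted p = 0.467 with an estimated correlation). A beta-expansin homologue (AK107184) stood at -1.37 ± 0.21, Os-EXP-1 (AK069548) at -1.35 ± 0.45, EXPB11 (AK059638) at -1.28 ± 0.13 and EXPB6 (AK101728) at -0.44 ± 0.04. The call of AK069548 was lost without replicate 1 or 2 (adjusted p = 0.0796 and 0.0766) and that of AK101728 without replicate 2 (0.0502). The list was not called without replicate 1 (adjusted p = 0.0717) or on the arrays with the mutant in Cy3 (adjusted p = 0.0781).

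Of the marker lists for tissues other than the coleoptile, camera called that of the photosynthetic leaf and no other. The leaf list was lower, with 7 of 28 probes down and 1 up, the same counts adjusted over the list alone (median -0.08, camera adjusted p = 0.00732; adjusted p = 0.442 with an estimated correlation); the call was lost on the arrays with the mutant in Cy5 (adjusted p = 0.254). Its members with the smallest p were a photosystem II 23 kDa protein (AK065248, -0.46 ± 0.08), a *psaB* homologue (AK059927, -0.44 ± 0.12), CP26 (AK061295, -0.37 ± 0.03) and the D1 protein (AK103503, -0.29 ± 0.01). Calls of AK059927 and AK103503 were lost without replicate 1 (adjusted p = 0.0796 and 0.0587), and these and AK061295 without replicate 2 (0.0708, 0.0838 and 0.0612). Of 6 root-specific probes 2 were lower, also adjusted over the list alone, with RCc3 (AK062381) at -1.19 ± 0.47 and RCc2 (AK063090) at -0.31 ± 0.06; both calls were lost without replicate 1 (adjusted p = 0.107 and 0.0651) and without replicate 2 (0.0962 and 0.0884). The 6 root probes carry only 2 distinct descriptions, so they may stand for as few as 2 genes. The root list as a whole was not called by camera (median -0.46, adjusted p = 0.108). Its median was -0.65, -0.66 and 0.01 in replicates 1, 2 and 3, and camera called it without replicate 3 (adjusted p = 0.00872). No probe of the 13 for endosperm and embryo storage proteins passed in limma, where 3 had an unadjusted p under 0.05 (camera adjusted p = 0.444, 0 adjusted over the list alone). The list for vascular secondary walls held 1 measured probe, which was not called in limma either way, and was not tested.

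**Figure D3:**
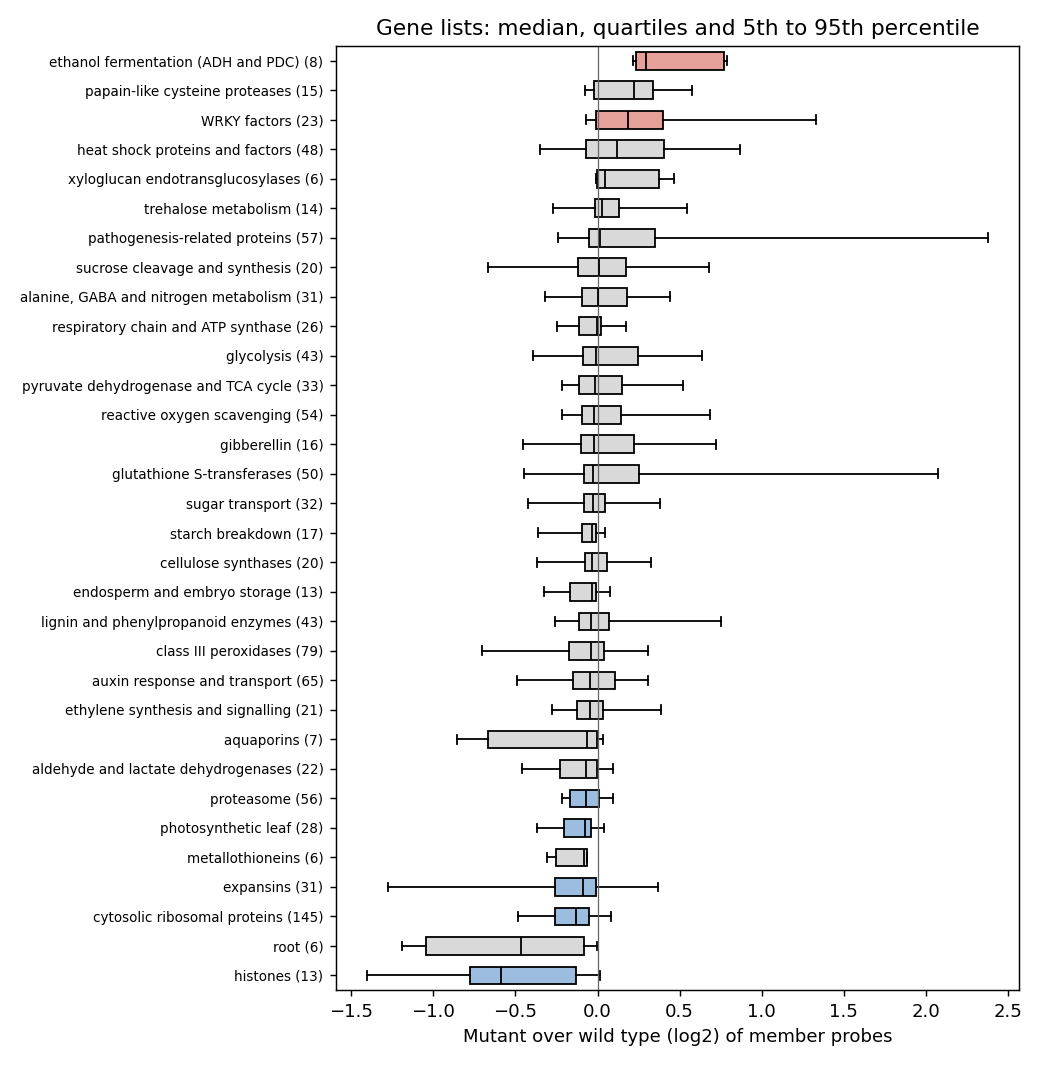
Log2 ratio of mutant over wild type (horizontal axis) of the member probes of the 32 gene lists tested, with the number of probes in brackets. Boxes show the median and quartiles and whiskers the 5th to 95th percentile; red and blue boxes are the lists called higher and lower by camera, from a median of 0.30 for ethanol fermentation to -0.59 for histones.

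In carbohydrate metabolism camera called no further list, whereas fry called sugar transport lower (adjusted p = 0.0292). In glycolysis 10 of 43 probes rose and 6 fell (10 and 7 adjusted over the list alone, camera adjusted p = 0.767), among them a pyruvate kinase-like cDNA at 0.70 ± 0.08 (AK071391) and GapB at -0.76 ± 0.10 (AK067755), the latter a plastid enzyme of photosynthesis. For sucrose cleavage and synthesis 4 of 20 rose and 4 fell (5 and 4 adjusted over the list alone, adjusted p = 0.966), with one invertase at 0.98 ± 0.04 (AK103334) and another at -0.66 ± 0.04 (AK072245). Starch breakdown had 1 of 17 up and 3 down, also adjusted over the list alone (adjusted p = 0.230), with a beta-amylase homologue at 1.71 ± 0.18 (AK068968) and a glucan phosphorylase at -0.80 ± 0.21 (AK103367). Sugar transport had 5 of 32 up and 5 down by either adjustment (adjusted p = 0.589), including a sugar transporter-like cDNA at -0.79 ± 0.10 (AK106658) and OsMST1 at -0.34 ± 0.03 (AK070018). In trehalose metabolism 1 of 14 rose by either adjustment, a trehalose 6-phosphate synthase homologue at 0.55 ± 0.17 (AK100050; list adjusted p = 0.554). Pyruvate dehydrogenase and the TCA cycle had 4 of 33 up and 3 down by either adjustment (adjusted p = 0.713), with NADP-isocitrate dehydrogenase at 1.09 ± 0.17 (AK072762) and a malate dehydrogenase homologue at -0.70 ± 0.19 (AK068064).

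Respiratory chain and ATP synthase had 2 of 26 up and 5 down by either adjustment (adjusted p = 0.565), with an NADH-ubiquinone oxidoreductase subunit at 0.43 ± 0.00088 (AK072342) and *atpC*, the gamma subunit of the chloroplast and not the mitochondrial ATP synthase, at -0.38 ± 0.08 (AK064835). Aldehyde and lactate dehydrogenases had 1 of 22 up and 5 down (2 and 5 adjusted over the list alone) and lay just past the threshold (median -0.07, adjusted p = 0.0554). OS-ALDH (AK060824) fell by 0.65 (SD 0.07) and a glutathione-dependent formaldehyde dehydrogenase (AK099733), which entered by its name, by 0.56 (SD 0.09). That list was called without replicate 2 (adjusted p = 0.0360) and on the arrays with the mutant in Cy3 (adjusted p = 0.0253). For alanine, GABA and nitrogen metabolism 5 of 31 rose and 2 fell (4 and 2 adjusted over the list alone, adjusted p = 0.647), including a glutamate decarboxylase (clone OsGAD1) at 0.83 ± 0.29 (AK061977) and a tRNA-glutamine synthetase at 0.34 ± 0.09 (AK065125), which charges tRNA and entered by its name. Of the haemoglobin probes 2 were measured, too few for a list test; Hb2 read 0.37 ± 0.21 (AK073898, adjusted p = 0.0519; 1 higher adjusted over the list alone) and haemoglobin 1 read 0.34 ± 0.76 (AK064054).

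Among stress and defence lists, heat shock proteins and factors had 18 of 48 probes up and 6 down (20 and 7 adjusted over the list alone). Camera fell just short of a call (median 0.12, adjusted p = 0.0554). The list was called without replicate 2 (camera adjusted p = 0.0331) and with a dye term and the replicate block (cameraPR adjusted p = 0.0476). Fry also called it higher (adjusted p = 0.0248). An HSP80 homologue (AK102426) rose by 0.80 ± 0.10. An HSP70 (AK109474) was also called higher, with a ratio of 0.84 on the 3 arrays where its mutant signal was saturated and 1.59 on the others, so its mean gives no exact size. Pathogenesis-related proteins had 13 of 57 up and 4 down by either adjustment (adjusted p = 0.252, but 0.0286 without replicate 1), including chitinases at 2.66 ± 0.33 (AK106319) and 1.76 ± 0.20 (AK106178). Glutathione S-transferases had 9 of 50 up and 5 down (10 and 6 adjusted over the list alone, adjusted p = 0.974), with OsGSTU3 at 1.87 ± 0.37 (AK061304) and a maize GST 13-like cDNA at -0.69 ± 0.11 (AK059955). Reactive oxygen scavenging had 6 of 54 up and 4 down (4 and 2 adjusted over the list alone, adjusted p = 0.981), with GPX1 at 1.61 ± 0.08 (AK062772) and a thioredoxin homologue at 1.42 ± 0.23 (AK058426). Class III peroxidases had 2 of 79 up and 12 down (2 and 11 adjusted over the list alone, median -0.04, adjusted p = 0.0554). They were called lower without replicate 2 (adjusted p = 0.0292), with the replicate as a block (0.0371) and by fry (0.0254). Members included homologues at -0.57 ± 0.06 (AK068894) and -0.42 ± 0.03 (AK109381). Metallothioneins had 1 of 6 down, at -0.40 ± 0.21 (AK105219), and 0 adjusted over the list alone (adjusted p = 0.214). That call was lost without any 1 of the 3 replicates (adjusted p = 0.0600, 0.106 and 0.0594) and on the arrays with the mutant in Cy5 (0.126).

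Papain-like cysteine proteases had 3 of 15 up and 0 down (4 and 0 adjusted over the list alone, camera adjusted p = 0.156), and fry called the list higher (adjusted p = 0.0248), but the members with the smallest p were protease inhibitors, at 0.56 ± 0.04 (AK073275) and, for oryzacystatin, 0.28 ± 0.07 (AK105278). Of 7 aquaporin probes 3 were lower by either adjustment, including an aquaporin at -0.86 ± 0.20 (AK103807) and a PIP2-2 homologue at -0.48 ± 0.09 (AK061491; list adjusted p = 0.169).

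Camera called no list of cell wall or hormone genes other than expansins. Xyloglucan endotransglucosylases, which remodel wall polymers, had 1 of 6 up, at 2.41 ± 0.31 (AK070734), and 1 down, at -0.88 ± 0.18 (AK059277), by either adjustment (adjusted p = 0.686). Cellulose synthases had 3 of 20 up and 3 down by either adjustment (adjusted p = 0.647), with a CSLD4 homologue at -1.27 ± 0.23 (AK067424) and CesA-1 at -0.32 ± 0.01 (AK100188). Lignin and phenylpropanoid enzymes had 5 of 43 up and 4 down by either adjustment (adjusted p = 0.589), with a 4-coumarate-CoA ligase-like cDNA at 1.69 ± 0.35 (AK105693) and a cinnamoyl-CoA reductase at 0.95 ± 0.18 (AK070746). For ethylene 3 of 21 rose and 3 fell by either adjustment (adjusted p = 0.312), with an ACC synthase homologue at 0.39 ± 0.01 (AK065212) and an ACC oxidase homologue at -0.36 ± 0.06 (AK102472). For auxin 6 of 65 rose and 7 fell (6 and 5 adjusted over the list alone, adjusted p = 0.306), with REH1 at -0.62 ± 0.04 (AK103208) and OsARF2 at 0.53 ± 0.05 (AK072309). For gibberellin 3 of 16 rose and 2 fell (5 and 2 adjusted over the list alone, adjusted p = 0.788), with GIGR2 at 0.46 ± 0.09 (AK073386) and a gip3 homologue at -0.46 ± 0.02 (AK059073).

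Of the 98 probes named under the fixed rule 94 were called, and none of these changed sign when any 1 replicate was left out. This was fixed in advance and shows nothing further, since all 4929 changed probes had the same sign in all 3 replicates. Without replicate 1, 35 of the 94 calls were lost, without replicate 2 36 and without replicate 3 5. In lists not called, other than root markers and metallothioneins, calls lost without replicate 1 were those of AK099733, AK103367, AK070018, AK068064, AK064835, AK065125, AK059277, AK100188, AK102472, AK073386, AK061491 and AK105278 (adjusted p 0.0513 to 0.0738). Those lost without replicate 2 were AK103367, AK100050, AK070018, AK064835, AK065125, AK100188, AK109381, AK065212, AK102472, AK073386, AK103807 and AK105278 (0.0513 to 0.112). Across lists, the median and mean had opposite signs for sucrose cleavage, glycolysis, sugar transport, the TCA cycle, the respiratory chain, lignin enzymes, reactive oxygen scavenging, glutathione S-transferases, ethylene and gibberellin.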

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

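The tests on replicate 3 were chosen after its values were seen. Across genes, the ratio depended on the dye: a limma test of the difference between the arrays with the mutant in Cy5 and those with the mutant in Cy3 called 5382 of 19947 probes, of which 1510 were also changed between genotypes. Such an effect has opposite signs in the 2 orientations and cancels in the mean of each dye-swap pair; no explanation for it was tested.

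Of the 4 sign patterns that 3 replicates allow, the real one gave 4929 called probes and was the 1 pattern with that many. The highest of the others gave 0 in limma, with 314 probes at an unadjusted p under 0.05. With 4 patterns a share under 0.05 cannot be reached.

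Replicate 3 stood apart from replicates 1 and 2. Whether its ratios were compressed as a whole was not decided. Medians of called lists, as a ratio of replicate 3 to the larger of the other replicates, ranged from 0.193 to 1.60, the latter for ethanol fermentation, which holds a saturated probe. Proteasome medians (-0.066, -0.055 and -0.087 in replicates 1, 2 and 3) and ribosomal protein medians (-0.11, -0.15 and -0.16) were also largest in size in replicate 3. Their SD over replicates was 0.016 and 0.024. Medians of expansins, WRKY factors, histones and leaf markers were not largest there. The higher of the correlations of replicate 3 with the other replicates was 0.840 against 0.885 between those. This restates what made replicate 3 stand out and is no separate test. The correlation within the dye-swap pair of replicate 3, 0.882, was the lowest of the 3 but near those of replicates 1 and 2 (0.887 and 0.896). This argues against noisier arrays only if the true ratios spread alike in each replicate, which was not tested. The lowest brightness is argued against by a median signal over background of 7.27 in replicate 3, between 6.51 in replicate 1 and 7.35 in replicate 2. The root marker list, whose 6 probes carry 2 descriptions, read -0.65, -0.66 and 0.01 in replicates 1, 2 and 3. A difference in the dissected tissue may therefore be involved. With the replicates' origin unlabelled this stays open, and no biological explanation was tested.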

How the results depend on the processing

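Chosen only after the data were seen were 1 probe per description, the ribosomal list without plastid descriptions, the fermentation list without its saturated probe and the list tests with the replicate block. Without 1 replicate, changed probes ranged from 1184 to 4573, those higher from 755 to 2746, those lower from 429 to 1827 and called fermentation probes from 0 to 3 (lists called, 7 to 10); each such fit has 1 residual degree of freedom fewer. Treating the 6 arrays as independent, with no replicate block, gave 7611 changed probes and 3375 lower ones, since technical repeats then count as replicates. With the replicate block 6781 probes were called, of which 4796 were among the 4929. The correlation within blocks was estimated at 0.206 there, against 0.632 with the dye term also fitted. Without the dye term, technical repeats may therefore still count in part as replicates. The *PDC1* probe AK100678 was lost with the block alone while AK102799 and AK073964 passed, and no other call of a named probe changed. With the dye term *PDC1* was called (limma adjusted p = 0.00149). List tests on the fit with the block alone called 8 lists, with class III peroxidases added (adjusted p = 0.0371) and no other list call changed. With the dye term also fitted 9 lists were called, heat shock proteins and factors among them (cameraPR adjusted p = 0.0476). All other settings for background, scaling, filter, dye orientation and variance gave 4812 to 5415 changed probes, apart from the dye term with its 6408; Aquantile scaling moves no ratio. *PDC1* alone changed sign, to -0.13 on the arrays with the mutant in Cy5 (adjusted p = 0.543); its Cy5 signal is saturated in both orientations, and the cause was not tested. Of 1762 comparisons of named probes with an alternative 1659 kept side and direction, 93 lost the call (76 of them without 1 replicate) and 9 gained it. These are not separate checks. Aquantile scaling and the filter settings left the ratios of named probes as they were, and the value table repeats the processed signals as deposited. With an estimated correlation camera called 0 lists (1 had an unadjusted p under 0.05), and fry, which does not compare a list with other genes, called 10. With 1 probe per identical description, the nearest run to the planned 1 probe per locus, 4 lists were called, against 7 with all probes. Without the saturated *PDC1* probe the fermentation list was not called (adjusted p = 0.0554). A slide term, other probes of a cDNA and means over probes were not run, because each slide held 1 array and each cDNA 1 probe. The lowest median signal, 3.998 times the background, limits dim probes.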

Other observations

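The 12 lists in this part were written after the largest changes had been seen, as were the test of root and leaf tissue and the bound of 0 for normalization and dye; the other tests were set before their values were seen. Genes of mitosis and the cell cycle were lower in the mutant: 37 of 85 probes fell and 3 rose (median -0.14, camera adjusted p over the 12 added lists 4.77e-06; adjusted p = 0.681 with an estimated correlation). They included cdc2 kinase (AK059682, -1.52), the partner of mitotic cyclins, and cyclin 2 (AK070518, -1.65). A MAP65-1a homologue (AK064024, -1.45), which bundles microtubules in the division apparatus, and topoisomerase II (AK063335, -1.41), which untangles chromosomes, were also lower. A CDC2C homologue (AK067238, 1.27) and an E2F (AK067581, 0.67) rose. Without the members already seen among the 60 largest changes in each direction, 27 of 75 fell and 3 rose (adjusted p = 0.000976). Core histones H2A and H2B, which the fixed histone list did not hold, fell in 7 of 9 probes (median -0.34, camera adjusted p = 0.000326). Leaving out members seen before, 6 of 8 fell (median -0.29, camera adjusted p = 0.00149). Of 31 tubulin and actin probes 8 fell and 1 rose (camera adjusted p = 0.00249). With an estimated correlation none of these lists was called (adjusted p = 0.681 for each).

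A candidate explanation is less cell division in the mutant coleoptile. For within-array normalization and for dye bias, the bound set beforehand for setting them aside was a median of the mitosis list under -0.2, and it was not met. The higher median was -0.15 with median centring or processed signals, and the medians in the 2 dye orientations were -0.13 and -0.22. By that bound normalization stays open as part of the cause, whereas a dye effect that adds to the ratio cancels in the mean of each dye-swap pair. A looser bound was set only after these values had been seen. All of these medians lay under 0 by more than their SD over replicates (at most 0.046) or arrays (at most 0.018). For dye bias this argues against it as the whole cause. For normalization it argues only against the choice between loess, median centring and processed signals. All of these centre the ratios of each array near 0, so a shift caused by that centring cannot be seen in this way. Less root or leaf tissue in the mutant sections cannot be told apart from less division, because the marker lists give no uniform answer. The root list differed from the mitosis list by -0.33, with RCc3 (AK062381) at -1.19, and the leaf list by 0.059. The probes of the root list carry only 2 descriptions. The root difference was -0.44, -0.54 and 0.15 in replicates 1, 2 and 3, and it was -0.25, -0.21 and -0.51 without each of them in turn, so replicate 3 went the other way. Dissection by laser was meant to remove both tissues. Genes of DNA replication, which should move with division, were not called (adjusted p = 0.124, median -0.034), which met the condition written beforehand for rejecting a shared shift. That condition was badly chosen, since a missed threshold does not show the absence of a shift and 9 of 38 probes fell while 1 rose; the test was therefore read as undecided after its result was known. The difference in genotype that the design names stays open and was not tested further.

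WRKY factors rose as a list by camera, though not with an estimated correlation (adjusted p = 0.442). Single chitinase and glutathione S-transferase cDNAs rose although their lists were not called (camera adjusted p = 0.252 and 0.974). A broader defence response may therefore be involved, and 6 further lists were tested for it without the members seen before. The test was whether NAC, calcium-binding, jasmonate, P450, glucosyltransferase and ABC transporter genes shift too. Camera called 0 of the 6 lists higher, and 0 were higher at an unadjusted p under 0.05. This met the condition written beforehand for rejecting the explanation. Fry, which asks only whether members move one way and does not compare them with other genes, called 3 of the 6 higher, and for that reason the result was read as undecided after it was known. With 24.7% of all tested probes called, such a fry call does not show that a list stands out from other genes. For comparison, 2920 of all 19947 tested probes rose and 2009 fell. Over all members, 12 of 55 ABC transporter probes rose and 2 fell (median -0.021), 9 of 31 NAC probes rose and 3 fell, and 12 of 65 calcium-binding probes rose and 5 fell. For cytochrome P450 11 of 94 rose and 9 fell, for glucosyltransferases 9 of 53 rose and 6 fell, and for jasmonate synthesis 4 of 26 rose and 2 fell; the medians of P450 and jasmonate were also below 0. Amino acid transport and synthesis (9 of 36 up, 2 down, adjusted p = 0.358) and translation factors (3 of 44 up, 6 down, adjusted p = 0.518) were not called.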
